A study of Mus musculus with 20 samples.

How the data were processed

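Mouse cells of 5 kinds were measured by RNA sequencing and by chromosome conformation capture carbon copy (5C), with 2 libraries per kind and assay and 20 libraries in all. Per the labels, they were V6.5 embryonic stem (ES) cells in medium with serum and LIF, the same line in 2i medium, primary neural progenitor cells (NPC) grown as neurospheres from whole brains of Sox2-eGFP mice at postnatal day 1, induced pluripotent stem (iPS) cells made from such NPC, and iPS cells in 2i medium. The 2i medium is serum-free and holds LIF and inhibitors of the kinases GSK3 and MEK (CHIR99021 and PD0325901). ES and iPS cells were grown on feeder fibroblasts and then passaged on gelatin to remove the feeders, per the labels' protocols. Replicates are not stated to be separate cultures, so p-values measure the spread between these samples, which may be technical.

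RNA libraries were made with a stranded, ribosomal-RNA-depleting total RNA kit from 350 ng of RNA and sequenced with 75 cycles per end, per the labels' protocols. The authors deposited whole-number counts of reads per transcript model, in the format of HTSeq. TopHat2 2.1.0, TopHat, HTSeq and the mouse assembly mm9 are named in the submitters' processing notes, and the counting mode and strand setting are not given in the sources used here. The design had foreseen counts per gene, but the files held 55419 transcript models, so a read overlapping several models of a gene counted as ambiguous, and the counts of overlapping and antisense models such as Xist and Tsix are uncertain. Of these models, 11767 could be named, through the 10334 symbols of an expression table that the authors deposited, which was used for names and positions only. No model carried the symbol Nanog. A model named Nanogpd in the Nanog region was tested under that name, and whether its reads are those of Nanog was not settled from the sources used here. The 92 spike-in entries and 5 summary entries stayed out of library sizes and tests. Reads assigned to a model were 7.36% to 37.9% of uniquely aligned reads, reads in no model 26.5% to 86.6% and ambiguous reads 6.00% to 35.6%.

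For 5C, cells were fixed with 1% formaldehyde and the chromatin was cut with HindIII, per the labels' protocols. In this method, pairs of primers for single restriction fragments are joined and amplified where 2 fragments were ligated. The authors deposited counts per pair of primers, with Bowtie and mm9 named in the submitters' processing notes. The 1551 primers covered 7 regions of 0.198 to 2.10 Mb, and 97243 forward and reverse pairs lay within a region. The authors also deposited binned contact frequencies on a log scale, read as log2 from their values, in bins of 20 kb at steps of 4 kb, quantile-normalized per the file headers, and a class for each of 32065 pairs of bins that was called on the 6 libraries of ES, NPC and iPS cells. The header of the 10-library table lists a class column that its lines do not hold, so its values were matched to the names from the first value after the distance. Coordinates are from mm9, counted from 1.

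RNA counts were fitted with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, low-count filter by expression, prior count 2) in R 4.3.3. All 10 libraries entered with the group as the only term, which left 5 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The filter kept 11031 models, 10355 of them with a symbol, and left out 44388. The dispersion corresponded to a biological coefficient of variation of 0.117. Gene lists written before the data were examined were tested with camera (limma 3.58.1), with a preset correlation and again with an estimated one. Of 31 lists, 26 had at least 3 measured members, which gave 182 tests over 7 contrasts. Counts of list members are of the measured ones, for example 14 of 20 naive, 11 of 15 core and 7 of 18 germline genes. For the trophoblast, Hox and astrocyte lists, 5 of 11, 7 of 19 and 3 of 10 genes were measured. The low-count filter can keep a model that is high in a single group. Members were matched by symbol only, so Tcfcp2l1, listed under its newer name, stayed out of the naive list. A symbol was represented by its model with the highest mean count. Levels are CPM, counts scaled to a common library size, with the SD over 2 libraries. A fold against a group without counts was computed against 3 counts per library and is a lower bound, and ratios against 1 to 3 counts carry a counting interval. Such bounds and intervals cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

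5C counts were fitted with the same test and design. Each pair was compared with the total of its own library, region and 1 of 20 distance strata, used as an offset, after a filter on a mean of at least 10 counts. The filter kept 75889 of the 96467 pairs that had a count and left out 20578. The coefficient of variation was 0.326, and 0.283 with a second kind of offset chosen after seeing the data, which also balanced each primer's total in each library over 30 rounds (primer-balanced offsets). The second kind removes the yield of single primers and also any real change spread over all contacts of a fragment. Of 10 pairs of windows fixed before the data were examined, 8 could be tested. The pairs with the Nanog promoter were not analysed here. Windows reached 10 kb to each side of a named position, except the wider window of the Klf4 downstream enhancers (chromosome 4, 55470347 to 55495347). Summed counts were tested in the same fit.

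A carry-over fraction placed iPS cells on the line from ES (0) to NPC (1). It is the covariance over models or primer pairs of the NPC minus ES difference with the iPS minus ES difference, with different ES libraries on either side so that no library is shared, divided by the covariance of the NPC minus ES difference between the replicates. Its error came from leaving out each of 20 blocks of models, or each of the 7 regions, and it has no p-value. For 2 contrasts that share the ES libraries, 20 data sets of unchanged groups were simulated. In these, all 10 libraries, ES included, were drawn from 1 mean per model.

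The genes named were chosen by a rule written before the data were examined, as were the groups, contrasts, tests, lists and other settings. It names the genes of the 5C regions, the 6 largest rises and 6 largest falls per contrast among models past the threshold with a mean log2 CPM of at least 3, a symbol that is not a predicted-gene name and both libraries of one group above both of the other, up to 4 members per list with the smallest p, 5 sex-linked markers, and up to 10 genes of the 5C regions called between iPS and ES cells. For 5C it names all fixed pairs and, per contrast, the 3 rising and 3 falling pairs with the smallest p, at most 1 per 40 kb window.

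Total counts ranged from 1.15M to 17.3M assigned reads per RNA library and from 10.5M to 26.5M counts per 5C library. No libraries were duplicates, since the counts of replicates differed by 3.25 to 38.7 times the sampling variance in RNA and by 9.61 to 13.6 times in 5C. The scripts were tested on simulated data with known changes. For iPS against ES cells, 22.0% of 82 models changed 1.5-fold, 45.5% of 55 changed 2-fold and 81.0% of 63 changed 4-fold were recovered in RNA. In 5C, the shares were 0%, 1.39% and 37.1% of 66, 72 and 62 changed pairs. With so few changed features, the adjusted threshold is stricter than in contrasts with many calls, to which the shares of both assays do not carry over. In contrasts with few calls, smaller changes of single 5C pairs were mostly not detectable.

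Other settings chosen at the same time were DESeq2 1.42.0 (size factors, and its Wald test), no filter and a stricter filter, a minimum of 2-fold, fits on only the groups compared, a replicate block, leaving out each replicate, fry in place of camera, other offsets, filters and distances in 5C, and other settings of the carry-over fraction and the classes. The primer-balanced offsets, a share of the iPS minus ES difference remaining in 2i, and fits without the 2 RNA libraries of highest no-feature share were added after seeing the data. Tables were handled with data.table (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.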

Results

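The series measured RNA and local chromosome folding in mouse ES cells, NPC and NPC-derived iPS cells, with ES and iPS cells also grown in 2i medium. Each of the 5 groups had 2 RNA and 2 5C libraries. Assigned RNA reads were 17.3M and 3.73M in ES cells, 15.6M and 14.5M in ES cells in 2i, 1.15M and 3.64M in NPC, 5.44M and 6.18M in iPS cells, and 4.90M and 9.62M in iPS cells in 2i. Replicates correlated at 0.960 in NPC and at 0.982 to 0.989 in the other groups, over transcript models, which are not independent replicates. Reads in no model made up 86.6% in NPC replicate 1 and 81.5% in ES replicate 2, and 26.5% in ES replicate 1. 5C totals were 26.5M and 25.8M in ES cells, 11.8M and 14.2M in ES cells in 2i, 14.9M and 14.7M in NPC, 12.2M and 12.9M in iPS cells, and 10.5M and 12.1M in iPS cells in 2i. The 7 regions held the genes Pou5f1, Nanog, Sox2, Klf4, Nes, and Olig1 with Olig2, and a gene desert.

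The first comparison asked how primary NPC differ from ES cells. Pou5f1, the pluripotency factor Oct4 (chromosome 17, 35642984 to 35647722), had 1160 and 1117 CPM in the ES libraries and no count in either NPC library, so it was at least 453-fold lower. Olig1 and Olig2, transcription factors of the oligodendrocyte lineage that lie next to each other (chromosome 16, 91270014 to 91272184 and 91225795 to 91228922), rose from 18.5 ± 2.16 to 4095 ± 582 CPM (SD, n = 2) and from 32.9 ± 2.59 to 1743 ± 201 CPM. Sox2, which is active in both cell types (chromosome 3, 34548927 to 34551382), fell from 527 ± 70.2 to 249 ± 3.05 CPM, and Klf4 (chromosome 4, 55540009 to 55545347) from 89.4 ± 8.04 to 10.1 ± 0.0666 CPM. Nes, the intermediate filament gene of neural stem cells (chromosome 3, 87775015 to 87777313), rose by 4.00 in log2, although the named model held only 3.70 CPM in NPC. The adjusted p from edgeR was 9.48e-08 for Sox2, 3.14e-14 for Klf4, 4.92e-05 for Nes and 1.88e-24 for Olig1.

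All 14 naive pluripotency genes and all 11 core pluripotency genes were lower in NPC, over all models and adjusted over the list alone. Dppa5a was at least 1024-fold lower, Tcfcp2l1 at least 526-fold, the threonine dehydrogenase gene Tdh at least 517-fold and Lin28a at least 479-fold. The list medians were -4.96 and -4.74 in log2 with genes at 0 placed at their bound, and -9.70 and -9.60 as fitted. The camera adjusted p was 5.86e-08 for the naive and 4.68e-06 for the core list, and both calls held with adjusted p = 0.0429 with an estimated correlation. Of 19 neural progenitor genes, 17 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 7.67e-08, and adjusted p = 0.119 with an estimated correlation). Among them, the proteoglycan gene Ncan rose by 6.17 in log2 and the transcription factor gene Pou3f3 by 8.64. Among genes that passed the naming rule, which asks for a mean log2 CPM of at least 3 over all 10 libraries, the largest rises were those of Acsbg1, Olfm2, Olig1, Mmp15, Fam181b and Chst7, from 7.42 to 9.79 in log2, and Acsbg1 went from 1.38 to 1128 ± 176 CPM.

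Genes of sterol synthesis were higher in NPC, with 8 of 12 rising and 1 falling, the same counts adjusted over the list alone (camera adjusted p = 0.0141, and adjusted p = 0.231 with an estimated correlation). Dhcr7, the last enzyme of cholesterol synthesis, rose by 2.33, Fdps by 1.85 and Nsdhl by 1.76 in log2. All 5 trophoblast markers were lower in NPC, both ways of adjustment (camera adjusted p = 0.0063, and adjusted p = 0.246 with an estimated correlation). The keratin genes Krt8 and Krt18 had no count in NPC and were at least 82.7-fold and 46.5-fold lower. Of 7 germline genes, 6 fell and 1 rose, both ways of adjustment (camera adjusted p = 0.0273, and adjusted p = 0.264 with an estimated correlation). Fibroblast markers went both ways, with 3 of 10 rising and 7 falling (camera adjusted p = 0.0861). Of 14 p53 targets, 7 rose, or 8 adjusted over the list alone, and 2 fell. Their median was 0.85 in log2 and camera pointed up (adjusted p = 0.17), whereas fry pointed down (adjusted p = 0.604). In edgeR, 6729 of 11031 models differed, 3013 up and 3716 down, and 5257 of them by at least 2-fold. The median model lay at -0.21 in log2 between NPC and ES cells and at 0.16 between iPS cells and NPC, and changes are to be read relative to it.

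Between iPS cells and the NPC they came from, the question was how far expression was reset. Pou5f1 was at least 1356-fold higher in iPS cells, Lefty1, an inhibitor of Nodal signalling, at least 616-fold, and Dppa5a at least 433-fold. Among genes past the same abundance rule, Fam181b, Olig1, Ncan, Acsbg1, Olig2 and Mmp15 had the largest falls, from -6.66 to -9.35 in log2. Sox2 fell further by 1.12 in log2, to 114 ± 4.63 CPM (edgeR adjusted p = 1.07e-07). Of the naive pluripotency genes, 13 of 14 rose and none fell, of the core genes 10 of 11 rose and 1 fell, and of the neural progenitor genes 16 of 19 fell and 2 rose. Adjusted over the list alone, the counts were the same, except that 17 neural progenitor genes fell. The camera adjusted p was 1.8e-07 for the naive, 7e-05 for the core and 1.8e-07 for the neural list, with 0.0705, 0.0705 and 0.113 as adjusted p with an estimated correlation. In total 5663 models differed, 3235 up and 2428 down.

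Several groups outside pluripotency were higher in iPS cells than in NPC. All 7 measured Hox genes, which pattern the body axis, rose, both ways of adjustment (camera adjusted p = 0.00301, and adjusted p = 0.113 with an estimated correlation). Fibroblast markers rose in 8 of 10 cases and fell in 1, both ways of adjustment, led by Tagln with 8.68, Col1a1 with 7.42 and Acta2 with 6.36 in log2 (camera adjusted p = 0.00611, and adjusted p = 0.32 with an estimated correlation). Of 15 glycolysis genes, 13 rose and none fell, both ways of adjustment, among them the glucose transporter gene Slc2a1 with 4.35 and Hk2 with 3.57 (camera adjusted p = 0.00159, and adjusted p = 0.32 with an estimated correlation). Sterol synthesis genes fell in 6 of 12 cases and rose in 1, both ways of adjustment (camera adjusted p = 0.00611, and adjusted p = 0.158 with an estimated correlation). Trophoblast markers rose in all 5 cases and formative epiblast genes in 10 of 14 with 4 falling, both ways of adjustment. Heat shock genes rose in 7 of 11 cases, or 8 adjusted over the list alone, and germline genes in 4 of 7, or 5, with 1 falling. Chromatin architecture genes fell in 6 of 11 cases and rose in 1, both ways of adjustment, with the cohesin subunit gene Smc1a at -1.82. The camera adjusted p of these 5 lists ran from 0.00185 to 0.0441, and from 0.158 to 0.32 with an estimated correlation.

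The iPS and ES cells, both in serum and LIF, were compared to ask how they differ after reprogramming. The iPS cells came from NPC of Sox2-eGFP mice and the ES cells were the V6.5 line. Differences of line or genotype thus cannot be told from those left after reprogramming. Pou5f1 was higher in iPS cells, at 3405 ± 697 against 1139 CPM (SD, n = 2), and Klf4 was higher at 319 ± 55.7 against 89.4 ± 8.04 CPM. Sox2 was lower, at 114 ± 4.63 against 527 ± 70.2 CPM. The log2 changes were 1.58, 1.84 and -2.20 (edgeR adjusted p = 8.52e-11, 1.37e-12 and 8.71e-14). These counts cannot separate endogenous transcripts from any introduced copy of a reprogramming factor. Olig1 did not pass the test, with 17.2 ± 0.441 CPM in iPS cells (log2 change -0.07, edgeR adjusted p = 0.795), and Olig2 fell to 15.1 ± 1.65 CPM. Nes did not pass either (log2 change 1.01, edgeR adjusted p = 0.417). Under the abundance rule for named genes, the largest rises were those of Ptprv, Shisa3, Klk1, Nat8l, Heg1 and Dmrta2, from 4.99 to 6.26 in log2. Under that rule, the largest falls were those of Ankrd45, Fabp3, Tcfcp2l1, Manba, St8sia1 and Npl, from -3.52 to -4.61, and Tcfcp2l1 encodes a transcription factor of naive pluripotency.

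**Figure D1:**
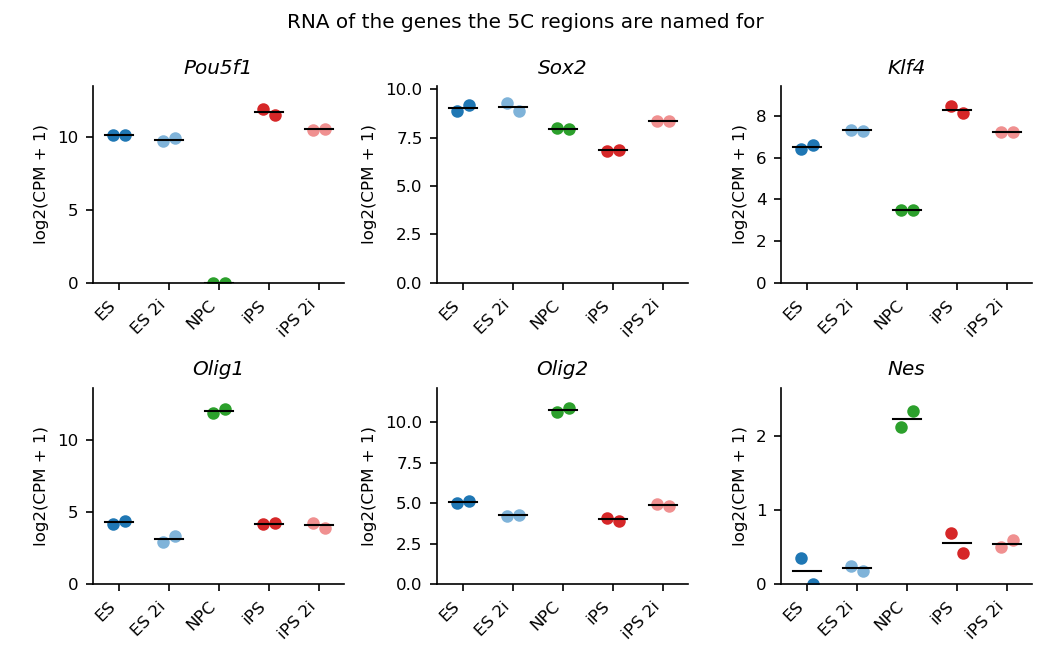
RNA of the 5C region genes, as log2(CPM + 1) on the vertical axis, for each library of the 5 groups (points), with a line at the mean of the log values. Pou5f1 is at 0 in both NPC libraries, and Sox2 is lowest in iPS cells, where its mean was 114 CPM.

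Naive pluripotency genes were lower in iPS cells, with 13 of 14 falling and Klf4 rising, both ways of adjustment (camera adjusted p = 0.000116, and adjusted p = 0.114 with an estimated correlation). Dppa3, a maternal factor that protects DNA methylation in early embryos, fell by 3.82, Zfp57, which guards imprints, by 2.58 and Tdh by 1.76 in log2. Of the core pluripotency genes, 8 of 11 fell and 1 rose, both ways of adjustment, without a call for the list (camera adjusted p = 0.0591). All 7 Hox genes rose, both ways of adjustment, with a median of 4.26 in log2 (camera adjusted p = 0.000187, and adjusted p = 0.114 with an estimated correlation). Hoxa4 went from 0.628 to 29.04 ± 4.72 CPM and Hoxb2 from 0.797 to 18.4 ± 3.15 CPM. The list holds 19 Hox genes, of which these 7 were measured. Hoxa4 and Hoxb2 may have passed the low-count filter through the iPS libraries alone. The rise of all 7 and the list test may thus be partly set by the filter. This also holds for the Hox results against NPC and for those of 2i in iPS cells. All 14 replication-dependent histone genes, a list that includes H2afx, rose by a median of 1.195, both ways of adjustment (camera adjusted p = 0.000116, and adjusted p = 0.494 with an estimated correlation). The linker histone gene Hist1h1b went from 1146 ± 148 to 2868 ± 349 CPM.

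Fibroblast markers were higher in iPS cells, with 7 of 10 rising and none falling, both ways of adjustment (camera adjusted p = 0.0493, and adjusted p = 0.522 with an estimated correlation). The collagen genes Col3a1 and Col1a1 rose by 2.69 and 2.49 in log2, and Acta2, smooth muscle actin, from 755 ± 104 to 1618 ± 86.8 CPM. Chromatin architecture genes fell in 6 of 11 cases and rose in none, both ways of adjustment (camera adjusted p = 0.0493, and adjusted p = 0.341 with an estimated correlation). Ctcf, which encodes an insulator protein, fell by 1.83, and Rad21, a cohesin subunit gene, fell by 1.57. Of 14 formative epiblast genes, 8 rose and 2 fell, both ways of adjustment, without a call (camera adjusted p = 0.0952), with Zic2 up by 3.83 and Lefty1 by 3.76. Neural progenitor genes rose in 7 of 19 cases and fell in 3, both ways of adjustment, without a call (camera adjusted p = 0.324), with Sox1 up by 3.49 and Vim, vimentin, by 1.65. Meg3, the maternally expressed RNA of the Dlk1-Dio3 imprinted domain, fell from 15.2 ± 0.222 to 0.686 ± 0.488 CPM (edgeR adjusted p = 2.64e-10). Of 10 other imprinted genes, 6 fell and 2 rose, both ways of adjustment, without a call (camera adjusted p = 0.203), with Peg10 and Impact at -2.28 and -2.16 and Peg12 up by 2.93.

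**Figure D2:**
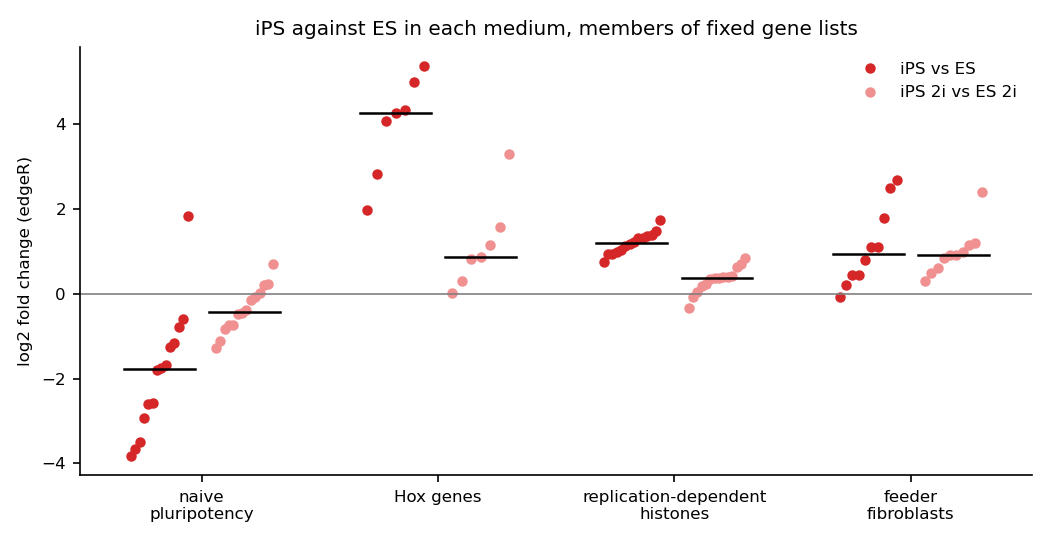
Log2 fold changes of the measured members of 4 gene lists (points), iPS against ES cells in serum and LIF (red) and in 2i (pink), with a line at the median. All 7 Hox genes and all 14 histone genes lie above 0 in serum and LIF, and 13 of 14 naive genes lie below.

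Of the genes within the 5C regions, Crabp2 and Lmna of the Nestin region had the largest rises in iPS cells, 4.39 and 2.82 in log2. Crabp2 binds retinoic acid and went from 17.1 to 363 ± 37.3 CPM, and Lmna, which encodes lamin A and C, went from 47.8 to 340 ± 46.8 CPM. In the Nanog region, a model named Nanogpd (chromosome 6, 122657586 to 122663796), which was not resolved from Nanog itself, fell from 30.7 ± 11.8 to 3.795 ± 0.41 CPM (edgeR adjusted p = 1.18e-10), with no count in NPC and 29.6 ± 5.69 CPM in iPS cells in 2i. In the Oct4 region, 26 of 55 measured genes rose and 9 fell, among them Nrm and Abhd16a with rises of 1.67 and 1.84. In edgeR, 5830 of 11031 models differed between iPS and ES cells, 2862 up and 2968 down, and 3833 of them by at least 2-fold. Reads in no model were 75.8% and 68.4% in the iPS libraries and 26.5% and 81.5% in the ES libraries. A fit chosen after seeing the data left out NPC replicate 1 and ES replicate 2, the libraries with the highest such share. It left ES replicate 1, with the lowest share, alone against the iPS libraries. That fit thus cannot tell an effect of this share from the difference between iPS and ES cells.

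How much of this difference lay on the side of NPC was asked next. Of 2366 models at least 2-fold higher in NPC than in ES cells, 1169 (49.41%) were also higher in iPS than in ES cells, 148 were lower and 1049 were not called. Of 2891 models at least 2-fold lower in NPC, 1640 (56.73%) were also lower in iPS cells, 310 were higher and 941 were not called. The contrasts share the ES libraries. In both, 1545 models rose and 2035 fell, against 781.7 and 999.8 for independent lists of that size and 0 in simulated unchanged groups. Unchanged groups give few calls at all, so this 0 does not show what the shared libraries add to real changes. The correlation over models was 0.366 and 0.297 when simulated, and the covariance was 1.74 and 0.063 when simulated, a difference of 1.67. Part of the excess overlap may come from the shared controls, since a split would leave 1 ES library on each side. The carry-over fraction of iPS cells was 0.229 ± 0.00729, on the line from 0 in ES cells to 1 in NPC. The iPS cells and NPC share a source of mice that the ES cells do not. Differences of line or genotype may thus enter this fraction and the overlap.

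In ES cells, 2i medium was compared with serum and LIF to show the response to this medium, which inhibits MEK and GSK3. Egr1, an immediate early gene downstream of ERK, fell by 3.81, and the ERK feedback genes Dusp4, Spry4 and Dusp6 by 2.08, 1.59 and 1.18 in log2. Of 16 genes that respond to this pathway, 11 fell and 1 rose, both ways of adjustment (camera adjusted p = 1.84e-05, and adjusted p = 0.224 with an estimated correlation). Of 17 WNT target genes, a pathway that GSK3 restrains, 5 fell and 1 rose, or 6 and 2 adjusted over the list alone, without a call (median -0.49, camera adjusted p = 0.0801), with Sp5 at -3.04 and T at -2.94. All 5 trophoblast markers fell, both ways of adjustment, and Krt8 went from 208 to 24.3 CPM (camera adjusted p = 5.43e-06, and adjusted p = 0.21 with an estimated correlation). Of 7 germline genes, 6 rose and none fell, both ways of adjustment, with Tuba3a up by 2.95 and the piRNA pathway gene Piwil2 by 1.54 (camera adjusted p = 0.000456, and adjusted p = 0.21 with an estimated correlation). Sohlh2, a germ cell transcription factor gene, had the largest rise under the abundance rule for named genes, from 10.7 to 213 CPM. Prdm14, which represses DNA methylation genes, rose from 15.8 ± 2.63 to 69.5 ± 8.51 CPM. Thbd, Krt19, S100a4, Egr1, Rgs16 and Id2 had the largest falls under that rule, from -3.50 to -4.15.

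Formative epiblast genes fell in 8 of 14 cases and rose in 1, or 2 adjusted over the list alone (camera adjusted p = 0.00122, and adjusted p = 0.224 with an estimated correlation), with Pou3f1 at -2.55, Lefty1 at -1.94 and Zic2 at 2.52 in log2. Fibroblast markers fell in 6 of 10 cases, or 7 adjusted over the list alone, and rose in 2 (camera adjusted p = 0.00252, and adjusted p = 0.342 with an estimated correlation). Tagln fell by 2.72 and Acta2 by 2.24, while Col3a1 rose by 2.78, from 17.4 to 116 CPM. Glycolysis genes fell in 6 of 15 cases, both ways of adjustment, with Pfkl at -1.35 and Tpi1 at -1.21 in log2 (camera adjusted p = 0.0119, and adjusted p = 0.367 with an estimated correlation). Only 3 of 10 astrocyte markers were measured. All 3 fell, both ways of adjustment (camera adjusted p = 0.00122, and adjusted p = 0.21 with an estimated correlation). Among them, Apoe, which carries lipids, was at -2.31 in log2. Targets of p53 fell in 6 of 14 cases, primitive endoderm markers in 3 of 4, and neural progenitor genes in 9 of 19 with 2 rising. These counts were the same adjusted over the list alone, except that all 4 endoderm markers fell. The camera adjusted p was 0.00749, 0.0119 and 0.0127, with 0.342, 0.21 and 0.342 as adjusted p with an estimated correlation. Naive pluripotency genes were split, with 3 of 14 rising and 5 falling, both ways of adjustment. Their median was 0.05 and their mean -0.07, and camera pointed down (adjusted p = 0.744). Pou5f1, Sox2 and Nes did not pass the test, with log2 changes of -0.32, 0.07 and -0.46 (edgeR adjusted p = 0.0874, 0.765 and 0.787), Klf4 rose by 0.84, and Olig1 and Olig2 fell by 1.204 and 0.86. None of 11 chromatin architecture genes passed edgeR at an adjusted 0.05. In total 2705 models differed, 1249 up and 1456 down, and 1444 of them by at least 2-fold. With the DESeq2 Wald test, 793 rose and 1192 fell.

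In iPS cells, 2i medium moved more models, 4701, of which 2324 rose and 2377 fell, 2749 of them by at least 2-fold. Sox2 rose from 114 ± 4.63 to 328 ± 1.18 CPM, Pou5f1 fell from 3405 ± 697 to 1493 ± 19.3 CPM, and Klf4 fell from 319 ± 55.7 to 151 ± 1.24 CPM (edgeR adjusted p = 3.09e-10, 3.14e-08 and 6.68e-08). Naive pluripotency genes rose in 11 of 14 cases and fell in 2, both ways of adjustment (camera adjusted p = 0.000482, and adjusted p = 0.167 with an estimated correlation), and Prdm14 went from 2.56 to 52.9 CPM. Hox genes fell in 6 of 7 cases, and in all 7 adjusted over the list alone (camera adjusted p = 0.000362, and adjusted p = 0.167 with an estimated correlation). Hoxa4 went to 1.22 and Hoxb2 to 0.713 CPM, and their falls may be partly set by the low-count filter, as stated above. All 14 histone genes fell, both ways of adjustment (camera adjusted p = 0.000482, and adjusted p = 0.366 with an estimated correlation). Fibroblast markers fell in 8 of 10 cases and rose in 1, both ways of adjustment, and Acta2 went to 366 CPM (camera adjusted p = 0.00354, and adjusted p = 0.366 with an estimated correlation). Formative epiblast genes fell in 10 of 14 cases and rose in 3, both ways of adjustment, and Lefty1 went from 1546 ± 41.7 to 75.2 CPM (camera adjusted p = 0.000506, and adjusted p = 0.278 with an estimated correlation). Germline genes rose in 6 of 7 cases, both ways of adjustment, with Rpl10l up by 4.82 (camera adjusted p = 0.000506, and adjusted p = 0.18 with an estimated correlation). WNT target genes fell in 6 of 17 cases, or 7 adjusted over the list alone, and rose in 4, without a call (camera adjusted p = 0.159). As in ES cells, genes downstream of ERK fell, in 9 of 16 cases with 2 rising, and Egr1 fell by 3.37. Trophoblast markers fell in 4 of 5 cases and rose in 1, neural progenitor genes fell in 8 of 19 and rose in 2, and glycolysis genes fell in 8 of 15 and rose in 1. Adjusted over the list alone, these counts were the same, except that 9 glycolysis genes fell. The camera adjusted p of these 4 lists ran from 0.0106 to 0.031, and from 0.334 to 0.366 with an estimated correlation.

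Compared directly, the response to 2i differed between iPS and ES cells in 3011 models, with 1667 responding more upward in iPS cells and 1344 more downward. The naive list differed upward, in 12 of 14 genes with 1 downward, both ways of adjustment (camera adjusted p = 2.76e-05, and adjusted p = 0.122 with an estimated correlation). The Hox list differed downward in 5 of 7 genes, both ways of adjustment (camera adjusted p = 0.000598, and adjusted p = 0.122 with an estimated correlation). The histone list differed downward in 11 of 14 genes, or 13 adjusted over the list alone (camera adjusted p = 0.000443, and adjusted p = 0.642 with an estimated correlation). The germline list differed upward in 4 of 7 genes and the core list in 4 of 11 with 1 downward, both ways of adjustment (camera adjusted p = 0.0259 and 0.0413, and adjusted p = 0.372 and 0.336 with an estimated correlation). Sox2 responded by 1.45 more, Klf4 by -1.92 and Zic2 by -4.33 (edgeR adjusted p = 1.18e-06, 5.39e-09 and 5.38e-15). The responses, which share no library, correlated at 0.473 over models, with 609 models rising and 723 falling in both, against 263.1 and 313.7 for independent lists.

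Between iPS and ES cells that were both in 2i, fewer models differed, 2794 with 1514 up and 1280 down, and 957 of them by at least 2-fold. Without a filter on low counts the split was 1087 up and 1382 down. Without ES 2i replicate 1 the count was 1463, and without iPS 2i replicate 1 it was 1618. Sox2 fell by 0.75 and Pou5f1 rose by 0.71 in log2 (edgeR adjusted p = 0.000118 and 0.000271), and Klf4 did not pass (log2 change -0.07, adjusted p = 0.727). Crabp2 had the largest rise under the abundance rule for named genes, 4.30, at 132 CPM in iPS cells against 6.73 in ES cells. Meg3 was lower, at 0.561 ± 0.0761 against 12.8 ± 3.24 CPM (edgeR adjusted p = 8.86e-10). Fibroblast markers rose in 8 of 10 cases, or 9 adjusted over the list alone (camera adjusted p = 0.00108, and adjusted p = 0.412 with an estimated correlation). Targets of p53 rose in 6 of 14 cases, or 7 adjusted over the list alone, with Perp up by 1.23 and Phlda3 by 1.25 (camera adjusted p = 0.00108, and adjusted p = 0.395 with an estimated correlation). Neural progenitor genes rose in 9 of 19 cases and fell in 2, or 3 adjusted over the list alone, with Egfr up by 2.31 (camera adjusted p = 0.0225, and adjusted p = 0.474 with an estimated correlation). Trophoblast markers rose in 4 of 5 cases, both ways of adjustment, and oligodendrocyte markers in 2 of 4, or all 4 adjusted over the list alone, with the myelin gene Mbp up by 1.33 (camera adjusted p = 0.0195 and 0.00915, and adjusted p = 0.395 for both with an estimated correlation). Naive genes fell in 7 of 14 cases and rose in 1, both ways of adjustment, without a call (camera adjusted p = 0.19). The Hox list was not called either, with 2 of 7 rising, both ways of adjustment (camera adjusted p = 0.0504). The carry-over fraction was 0.0462 ± 0.00498, and -0.00535 ± 0.00546 for ES cells in 2i, which serve as a reference for the medium but not for line or genotype.

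Among the fixed 5C pairs, the largest difference between NPC and ES cells was that of the Olig1 and Olig2 promoters with distance offsets and that of Sox2 with its downstream control region with primer-balanced offsets. The window pair of the Olig1 and Olig2 promoters was at 8.93 ± 1.68 times the count of its distance in NPC and at 0.989 ± 0.0316 times in ES cells (SD, n = 2). The log2 change was 3.17 (edgeR adjusted p = 3.43e-11), and 0.61 with primer-balanced offsets (adjusted p = 0.000248). A pair of fragments next to these genes (chromosome 16, 91230344 to 91235133 with 91258013 to 91263997) had 7883 and 8411 counts in NPC and 668 and 589 in ES cells (log2 change 4.38, edgeR adjusted p = 8.53e-10, and 1.21 with adjusted p = 0.000262 when balanced). The Sox2 promoter and its downstream control region (chromosome 3, 34538927 to 34558927 with 34648927 to 34668927) met less in NPC, at 1.87 ± 0.669 against 4.74 ± 0.673 times the count of their distance (log2 change -1.34, edgeR adjusted p = 5.35e-05, and -1.05 with primer-balanced offsets). The Pou5f1 promoter and a window beyond Tcf19 met less as well (log2 change -1.02, edgeR adjusted p = 0.000219, and -0.99 balanced), and so did Klf4 and its downstream enhancers (-0.60, edgeR adjusted p = 0.0226, and -0.48 balanced). Olig2 with Mis18a rose by 1.46 (edgeR adjusted p = 0.000586) but not past the threshold when balanced (0.33, adjusted p = 0.253), and Nes with Bcan rose by 0.85 (edgeR adjusted p = 0.000627) and was at -0.06 when balanced. Olig2 with Urb1 was at 0.04 (edgeR adjusted p = 0.864) and fell by 0.77 only when balanced (adjusted p = 0.000248). Klf4 with Zfp462 was at 0.42 (edgeR adjusted p = 0.211) and rose by 0.68 only when balanced (adjusted p = 0.0226).

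Across the 75889 pairs tested, 13503 differed between NPC and ES cells in edgeR, 6749 up and 6754 down, and 9536 with primer-balanced offsets, 4617 of them shared. The share called was 20.7% in the Olig region, 19.3% in the Nanog, 19.2% in the Oct4, 18.2% in the Nestin, 17.6% in the gene-desert, 16.1% in the Sox2 and 12.8% in the Klf4 region. With 1 total per region in place of the distance strata, the split was 4119 up and 16660 down. Without ES replicate 1 the count was 7549, and without ES replicate 2 it was 6425, and 6075 and 3192 with primer-balanced offsets.

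**Figure D3:**
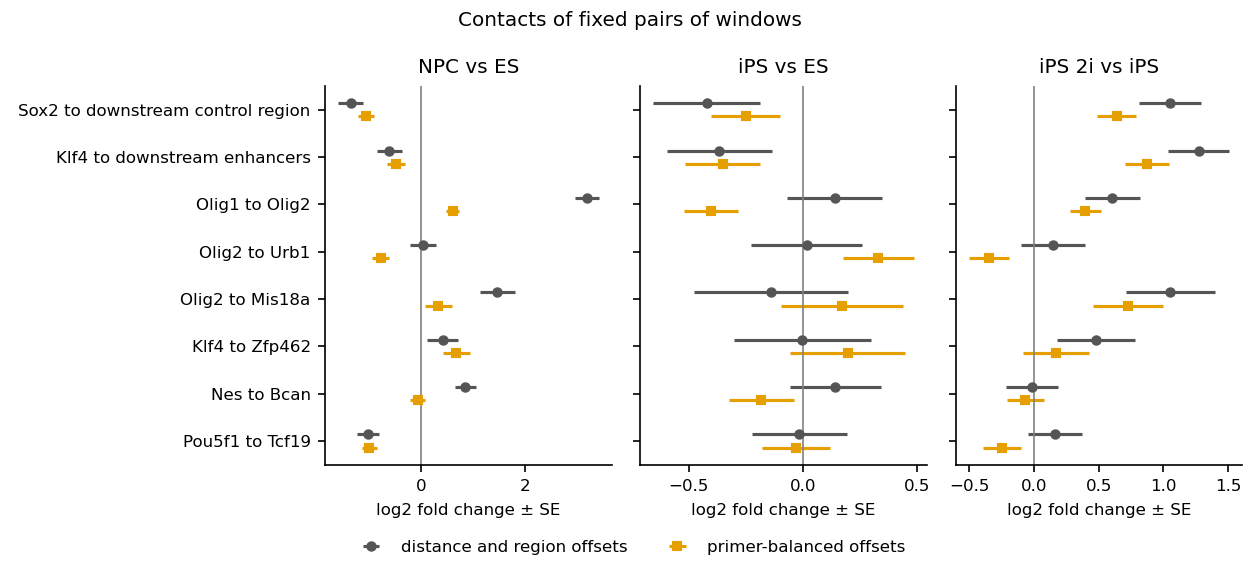
Log2 fold changes of the 8 fixed 5C window pairs with their standard error (bars), for NPC against ES cells, iPS against ES cells and 2i against serum and LIF in iPS cells, with distance offsets and with primer-balanced offsets. Sox2 with its downstream control region fell by 1.34 in NPC and rose by 1.05 in iPS cells in 2i.

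From NPC to iPS cells, the Olig1 and Olig2 promoter pair fell by 3.04 in log2 (edgeR adjusted p = 7.21e-11, and -1.01 balanced). The Sox2 pair rose by 0.92 (edgeR adjusted p = 0.00165, and 0.80 balanced) and the Pou5f1 and Tcf19 pair by 1.00 (edgeR adjusted p = 0.000351, and 0.96 balanced). Olig2 with Mis18a and Nes with Bcan fell by 1.60 and 0.71 (edgeR adjusted p = 0.000351 and 0.00328) but were at -0.16 and -0.12 when balanced (adjusted p = 0.56 and 0.528). Olig2 with Urb1 was at -0.0272 (edgeR adjusted p = 0.913) and rose by 1.10 only when balanced (adjusted p = 8.46e-06). Klf4 with its enhancers and with Zfp462 did not pass with either offsets (0.24 and -0.42, edgeR adjusted p = 0.363 and 0.245). A pair on the far side of Olig2 (chromosome 16, 91211055 to 91223417 with 91191865 to 91193395) had 4581 and 4057 counts in NPC and 257 and 244 in iPS cells (log2 change -3.79, edgeR adjusted p = 2.54e-08, and -2.54 with adjusted p = 1.05e-06 when balanced). In all, 4730 pairs differed, 3268 up and 1462 down, and 8333 with primer-balanced offsets, 2801 of them shared. The split was 19784 up and 1726 down with 1 total per region, and 3006 up and 4378 down with TMM scaling and no distance term. The count was 1331 without iPS replicate 1 and 2635 without NPC replicate 1. With primer-balanced offsets it was 2563 without iPS replicate 1, 4129 without iPS replicate 2 and 4675 without NPC replicate 1.

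Between iPS and ES cells, none of the 8 fixed pairs was called with distance offsets. The Sox2 pair was at 3.54 times the count of its distance in iPS cells (log2 change -0.42, edgeR adjusted p = 0.517), and the Olig1 and Olig2 pair at 1.09 ± 0.188 times (0.14, edgeR adjusted p = 0.99). The Olig1 and Olig2 pair was lower with primer-balanced offsets (-0.40, edgeR adjusted p = 0.0298). Among all pairs, 4079 differed, 2955 up and 1124 down, but with primer-balanced offsets only 18, of which 12 rose, 6 fell and 10 were shared. With TMM scaling and no distance term, 2528 rose and 2219 fell. Without ES replicate 1 the count was 1048, without ES replicate 2 it was 1463, and without iPS replicate 2 it was 1341. Balanced, it was 5 without either ES replicate, 10 without iPS replicate 1 and 1 without iPS replicate 2. A pair in the Sox2 region that spans 449 kb (chromosome 3, 34900011 to 34902586 with 34450023 to 34455379) had 1295 and 1366 counts in ES cells, 38 and 34 in iPS cells and 33 to 54 in the libraries of the other groups (log2 change -4.31, edgeR adjusted p = 1.66e-07, and -3.57 with adjusted p = 1.45e-05 when balanced). It was thus high in the ES libraries in serum and LIF alone. Its fragment at 34450023 also had fewer counts with 34204379 to 34210912, 3038 and 2505 in ES cells and 237 and 242 in iPS cells. That log2 change was -2.45 (edgeR adjusted p = 1.37e-05, and -1.75 with adjusted p = 0.00421 when balanced). These pairs share a fragment and are not independent. No named gene model overlapped these fragments. Neighbouring fragments near Olig1 (chromosome 16, 91315587 to 91318835 with 91318837 to 91324345) had 168 and 150 counts in ES cells and 1780 to 5953 in the other libraries, a rise of 4.72 in iPS cells (edgeR adjusted p = 2.86e-09) that was 0.41 with primer-balanced offsets (adjusted p = 0.392).

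**Figure D4:**
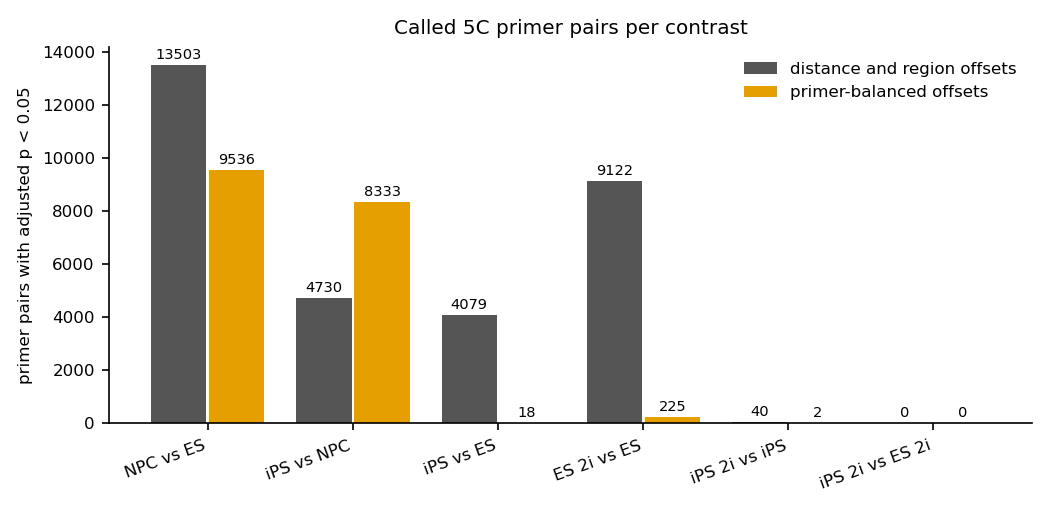
Number of 5C primer pairs past the threshold of 75889 tested (bars), for 6 contrasts, with distance offsets and with primer-balanced offsets. Calls between iPS and ES cells went from 4079 to 18 and those between ES cells with and without 2i from 9122 to 225.

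In 2i, the contact of Klf4 with its enhancers was higher in both ES and iPS cells with either offsets. Klf4 and its downstream enhancers (chromosome 4, 55535347 to 55555347 with 55470347 to 55495347) rose from 1.33 to 3.18 times the count of their distance in ES cells and from 1.03 to 2.49 times in iPS cells. The log2 changes were 1.26 and 1.27 (edgeR adjusted p = 9.89e-05 and 0.000185), and 0.65 and 0.87 with primer-balanced offsets (adjusted p = 0.00759 and 0.000541). The Sox2 pair rose by 0.56 in ES and by 1.05 in iPS cells (edgeR adjusted p = 0.0342 and 0.000892), and when balanced by 0.64 in iPS cells (adjusted p = 0.00217), with 0.36 in ES cells (adjusted p = 0.0586). Olig2 with Mis18a rose by 1.83 and 1.05, and by 0.94 and 0.72 when balanced. Klf4 with Zfp462 rose by 0.94 in ES cells (edgeR adjusted p = 0.00923, and 0.74 balanced). Olig1 with Olig2 rose by 0.61 in iPS cells (edgeR adjusted p = 0.0182, and 0.395 balanced), where the other 4 pairs did not pass with either offsets. In ES cells, the rises of Olig1 with Olig2 (0.82), Nes with Bcan (0.46) and the Pou5f1 and Tcf19 pair (0.64) were -0.21, -0.25 and -0.33 when balanced. The difference between the responses was called for none of the 8 fixed pairs with distance offsets (lowest edgeR adjusted p = 0.31, with none at an unadjusted 0.05), and for Olig1 with Olig2 when balanced (0.61, adjusted p = 0.0179).

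Over all pairs, 9122 differed between ES cells in 2i and in serum and LIF, 5158 up and 3964 down, but 225 with primer-balanced offsets, with 151 up, 74 down and 132 shared. With 1 total per region, 4233 rose and 5156 fell. The count was 4193 without ES replicate 1, 2634 without ES replicate 2, 3142 without ES 2i replicate 1 and 4926 without ES 2i replicate 2, and balanced it was 27, 7, 7 and 13. In iPS cells only 40 pairs differed with 2i, 36 up and 4 down, 28 of the rising ones in the Olig region, and 2 when balanced, none of them shared. That count was 0 without iPS replicate 1, 1 without iPS replicate 2 and 3 without iPS 2i replicate 1. The largest fall by p joined fragments in Lmna (chromosome 3, 88294862 to 88297660 with 88301987 to 88307432), by 1.45 in log2 (edgeR adjusted p = 0.0138, and -0.33 with adjusted p = 0.52 when balanced). The response differed between iPS and ES cells in 1577 pairs, 460 up and 1117 down, and in 1 pair when balanced. TMM scaling with no distance term gave 947 up and 1208 down. The count of 1577 fell to between 524 and 945 on leaving out any of 7 of the 8 libraries. It was 542 and 686 without ES replicate 1 or 2, 945 and 745 without ES 2i replicate 1 or 2, 524 without iPS replicate 2, and 606 and 919 without iPS 2i replicate 1 or 2. Between iPS and ES cells in 2i, edgeR called 0 pairs, with 3905 (5.15%) at an unadjusted p under 0.05, and 0 when balanced, with 1768 unadjusted. DESeq2 called 5.

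The position of iPS contacts between ES cells and NPC was measured by the carry-over fraction. It was 0.516 ± 0.0401 in iPS cells and 0.472 ± 0.04 in iPS cells in 2i, and 0.627 ± 0.0532 in ES cells in 2i, which did not come from NPC. In iPS cells it was 0.6255 without iPS replicate 1 and 0.4067 without iPS replicate 2. The error over regions does not measure this spread between libraries, so the order of iPS cells and ES cells in 2i is uncertain. With primer-balanced offsets the fraction was 0.126 ± 0.0437, 0.225 ± 0.0717 and 0.335 ± 0.0923, and 0.0622 in iPS cells without iPS replicate 2 and 0.189 without iPS replicate 1. In the authors' class of contacts shared by NPC and iPS cells, 200 pairs of bins, the mean distance-corrected log2 value was 0.167 in ES cells, 1.10 in NPC and 0.941 in iPS cells. In their 10-library table, the same bins were at 0.142, 1.05 and 0.878, and at 0.692 in ES cells and 0.561 in iPS cells in 2i. The class of contacts in ES cells alone, 2592 pairs of bins, was at 0.897 in ES cells, -0.0415 in NPC, 0.148 in iPS cells, 0.260 in ES cells in 2i and 0.373 in iPS cells in 2i. The authors chose these classes on the ES, NPC and iPS libraries, so the values there are not independent evidence. With 2 libraries against 2, no exact permutation test can go below 0.33, and none was run.

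**Figure D5:**
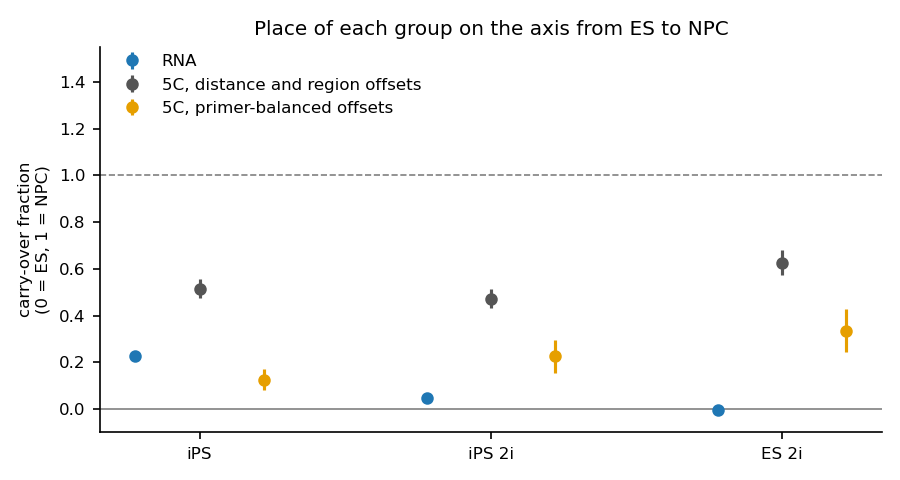
Carry-over fraction on a vertical axis from 0 (ES cells) to 1 (NPC) for iPS cells, iPS cells in 2i and ES cells in 2i, with its error from leaving out blocks of models or regions (bars), for RNA, 5C and 5C with primer-balanced offsets. In 5C, the points of ES cells in 2i, at 0.627 and 0.335 when balanced, lie above those of iPS cells. The bars do not measure the spread between libraries, and without iPS replicate 1 the iPS value was 0.6255 with distance offsets.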

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

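Of the tests in this part, those on thinned counts, on between-region counts and on the most abundant NPC genes were written before their result was seen, and those on primer-balanced offsets, the spread of naive genes, fibroblast genes, Eif2s3y and the pairs called again after thinning after.

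The response to 2i differed between iPS and ES cells in 3011 RNA models, 5 gene lists and 1577 5C primer pairs, by the edgeR and camera tests of that difference. None of the 5 lists was called with an estimated correlation, and only 1 pair was called with primer-balanced offsets. Counts that joined primers of different regions made up 7.95% to 18.9% of a 5C library. They enter none of the tests of pairs, and were used only to check primer yield below.

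The first pattern was that ES cells in serum and LIF stood apart in 5C from the other pluripotent cells, with 9122 pairs against ES cells in 2i. A difference in primer yield between library preparations fitted, since shifts of single primers correlated at 0.778 between contacts within and between regions, over 1544 primers that are not independent. The correlation was 0.863 for iPS and 0.707 for NPC against ES cells, and 0.363 for iPS cells against NPC. Calls of NPC against ES cells may thus share this shift. Primer shifts of the ES replicates correlated at 0.9355, so using different ES libraries on either side does not remove them from the 5C carry-over fraction. Greater depth of the ES libraries was excluded, since the count after thinning was 95.01% of the first, and 8107 of the 9122 pairs (88.87%) were called again in the same direction. Calls with primer-balanced offsets came to 2.47% of the first count, and were 929 against 10468 with a replicate block in both fits. They cannot exclude a response of single contacts to 2i, since fewer calls make the adjusted threshold stricter. At an unadjusted edgeR p under 0.05, 10017 pairs (13.2%) remained with these offsets, against 20351 (26.82%) with distance offsets. Yield cannot be told from a real change shared by all contacts of a fragment, including those with other regions.

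The second pattern was lower naive and higher Hox and fibroblast RNA in iPS than in ES cells. Remaining NPC with an unchanged profile were excluded as the cause. Over the 100 most abundant NPC genes, the 25th percentile of the iPS excess over ES cells was 0.116% of the NPC excess. At least 1.92% was foreseen for a shared source, given the 75th percentile of 7.70%. Cells left from NPC whose expression had changed in the new medium were not tested. Dilution of pluripotent cells was excluded as the whole cause of the low naive genes, since they did not fall alike, with 10 of 13 other than Klf4 (76.92%) more than 2 SE from their median, from Dppa3 at -3.82 to Gbx2 at -0.58. A smaller dilution stays open, since 8 of 11 core genes also fell, with a list median of -1.197 and Sox2 at -2.20. Feeder fibroblasts stay open, since the 90.0% of fibroblast genes higher in iPS cells restates the pattern, Col3a1 rose in iPS cells in 2i where 9 of 10 were lower, and cultures were passaged on gelatin to remove feeders. Other differentiated cells, with which feeders share these genes, and expression by the iPS cells themselves were not tested.

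The third pattern was Xist, the RNA that silences an X chromosome (chromosome X, 100655712 to 100678572), with 35 and 69 counts in iPS cells and 1 and 0 in ES cells, a ratio of 209.6 (counting interval 36.8 to 8357), and 75 and 125 counts (49.5 ± 18.8 CPM) in NPC. A share of cells with 2 X chromosomes and no Y would lower the Y-linked gene Eif2s3y, which was at -1.115 in log2 (edgeR adjusted p = 0.00456). From iPS cells to iPS cells in 2i, Xist fell from 9.48 ± 3.2 to 3.57 ± 0.696 CPM and Eif2s3y rose from 2.85 ± 0.537 to 12.85 ± 1.06 CPM (edgeR adjusted p = 0.00175 and 8.24e-07), as this explanation needs. It stays open, since Eif2s3y was also higher in iPS than in ES cells in 2i (0.67, adjusted p = 0.0343), and NPC had Eif2s3y at 7.68 ± 0.204 CPM beside Xist. Counts of Xist may include reads of the antisense gene Tsix, and no other biological explanation was tested for the -1.115 of Eif2s3y.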

How the results depend on the processing

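The primer-balanced offsets, the fits without 2 RNA libraries and the share remaining in 2i were chosen after the results were seen. Of 9839 comparisons of 784 single-gene RNA results with another setting, 9462 kept the side of the threshold and, where past it, the direction. The rest were 327 weaker, 50 stronger and 0 reversed. Of 891 comparisons of 92 single-pair 5C results, 797 were kept in this way, 70 became weaker, 5 stronger and 19 reversed. Those kept include 39 in RNA and 45 in 5C that changed sign with neither value past the threshold. With a minimum of 2-fold, fewer models by construction, the RNA counts were 3833 for iPS vs ES, 1444 for ES 2i vs ES, 2749 for iPS 2i vs iPS, 957 for iPS 2i vs ES 2i and 1926 for the 2i effect in iPS vs in ES. Leaving out 1 library, which leaves a single library assumed to vary like the other groups, gave 1463 to 2622 for iPS 2i vs ES 2i and stayed within 1.5 times in the other RNA contrasts. Of 182 list tests, 53 were called, 2 with estimated correlation, 116 with fry and 49 to 59 without 1 library. The RNA carry-over fraction of iPS was 0.206 with a pseudocount of 0.5 CPM and 0.221 to 0.2361 without 1 library. That of iPS 2i was 0.0359 with this pseudocount, 0.03942 at a mean CPM of at least 10 and 0.04429 to 0.04805 without 1 library. That of ES 2i was -0.01187 at a mean CPM of at least 10 and -0.009118 to -0.001584 without 1 library. The share of the iPS minus ES difference remaining in 2i was 0.3626 ± 0.00896, with 0.3757 and 0.3756 under the same settings and 0.345 to 0.3802 without 1 library. With primer-balanced offsets, the 5C counts were 8333 for iPS vs NPC, 18 for iPS vs ES, 225 for ES 2i vs ES, 2 for iPS 2i vs iPS and 1 for the 2i effect in iPS vs in ES. The construction removes shifts of whole primers, and the coefficient of variation went from 0.326 to 0.283. A smaller spread can raise a count, as that of iPS vs NPC rose, but its part in that rise was not tested. The same offsets reversed 15 results. For NPC vs ES they were Olig2 with Urb1 (-0.77) and Nes with Bcan (-0.0618), for iPS vs NPC Olig2 with Urb1 (1.10), and for iPS vs ES Olig1 with Olig2 (-0.40) and the pair at 90916300 and 90914093 on chromosome 16 (0.34). For ES 2i vs ES they were Olig1 with Olig2 (-0.21), Nes with Bcan (-0.25), Pou5f1 with the Tcf19 window (-0.33), the pair at 91357886 and 91318837 on chromosome 16 (-0.35) and that at 35909124 and 34946053 on chromosome 17 (0.39). For iPS 2i vs iPS they were the chromosome 16 pairs at 91050141 and 91053886 (-0.18), 90774315 and 90772508 (-0.15) and 90916300 and 90914093 (-0.22), and for the 2i effect in iPS vs in ES Olig1 with Olig2 (0.61) and the pair at 90916300 (-0.56). With 1 total per region, NPC vs ES gave 20779 pairs, iPS vs NPC 21510 and iPS 2i vs iPS 66, and reversed Olig2 with Urb1 (-0.73 and 1.018) and Klf4 with Zfp462 (-0.75 and 1.06) in NPC vs ES and iPS vs NPC. TMM without a distance term gave 7384 for iPS vs NPC and 180 for iPS 2i vs iPS. For 5C iPS 2i vs iPS, a mean of at least 50 counts gave 73, pairs at least 40 kb apart 9, and the DESeq2 Wald test 526. DESeq2 gave 5 for 5C iPS 2i vs ES 2i and 3355 for the 5C 2i effect in iPS vs in ES. For 5C iPS vs NPC, pairs at least 40 kb apart gave 2876 and only the libraries of the groups compared 2748. Libraries of the same replicate number, which no label pairs, correlated at -0.0801 to 0.0722 in RNA and -0.0419 to 0.161 in 5C. In 5C the between-region share was lower in replicate 1 than in replicate 2 of ES 2i (8.06% and 15.8%), iPS (9.32% and 16.1%) and iPS 2i (7.95% and 17.0%) but higher in NPC (15.4% and 10.7%), so a preparation shared by number was not excluded. A replicate block gave 137 for 5C iPS 2i vs iPS, and with primer-balanced offsets 98 for iPS vs ES, 929 for ES 2i vs ES and 29 for iPS 2i vs iPS. Without 1 library, 5C counts were 6425 to 10813 for NPC vs ES, 1331 to 3780 for iPS vs NPC, 1048 to 2759 for iPS vs ES, 2634 to 4926 for ES 2i vs ES, 0 to 37 for iPS 2i vs iPS and 524 to 1873 for the 2i effect in iPS vs in ES. Balanced, the same ranges were 3192 to 7516, 2563 to 7296, 1 to 10, 7 to 27, 0 to 3 and 0 to 4. The 5C carry-over fraction of iPS was 0.4336 with no distance term and 1 total per region, 0.3975 with the authors' bin values, 0.1257 with primer-balanced offsets, 0.4067 to 0.6255 without 1 library, and 0.06222 to 0.1891 without 1 library when balanced. That of iPS 2i was 0.3584 with bin values and 0.2252 balanced, and that of ES 2i 0.5042 and 0.3348. The authors' class of NPC and iPS contacts was at 0.8776 in iPS cells in the 10-library table. Apart from the settings whose construction is stated, the cause was not tested. The 2 fixed pairs of Nanog were not run. NPC RNA had the lowest depth, with 1.15M and 3.64M assigned reads, and ES replicate 2 was close at 3.73M. The effect of RNA depth was not tested.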

Other observations

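The share of iPS minus ES differences remaining in 2i was added after the results were seen, and the other values in this part come from tests chosen before.

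Some genes on the NPC side in iPS cells were there in 2i as well. Of the 1169 models higher in NPC and in iPS than in ES cells, 457 were also higher in iPS than in ES cells when both were in 2i, by the edgeR test on other libraries, and of the 1640 that were lower, 594 were also lower. From iPS cells to iPS cells in 2i, 854 of the 1169 fell and 1109 of the 1640 rose, toward the ES side. Over all 11031 models, 2377 fell and 2324 rose. The models were chosen with the same iPS libraries, so part of this shift may come from that choice. From iPS cells to iPS cells in 2i, Vim fell from 2289 ± 114 to 1044 CPM, while Acsbg1 stayed at 9.39 and 7.84 CPM (log2 change -0.18, edgeR adjusted p = 0.609). In ES cells in serum and LIF, Vim was at 731 and Acsbg1 at 1.38 CPM, levels that are not those of ES cells in 2i. Over all models, the share of the iPS minus ES difference that remained in 2i was 0.363 ± 0.00896. Differences of line or genotype between iPS and ES cells would enter this share as well.

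Meg3 was low in iPS cells in both media. It was at 0.686 ± 0.488 CPM in iPS cells and 0.561 ± 0.0761 CPM in iPS cells in 2i, and the response to 2i did not pass the edgeR test (log2 change -0.26, adjusted p = 0.812), nor did it in ES cells (-0.25, adjusted p = 0.498). The cause was not tested.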
